A study of Mus musculus with 8 samples.

How the data were processed

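The 8 libraries were analysed as 4 Jagn1 knockout and 4 control libraries, grouped by the sample titles and genotypes in the labels. Per the labels' protocols, RNA from sorted plasmablasts was extracted with Trizol and 500 ng of total RNA went into QuantSeq 3′ mRNA-Seq (FWD) libraries, which read the 3′ end of polyadenylated transcripts. Each deposited file holds whole-number read counts per gene symbol, not normalized. Per the submitters' processing notes, BWA 0.7.12, SAMtools 1.3.1, TopHat2 2.1.1, HTSeq 0.6.1 and the mm10 build were used; the role of each tool, the gene annotation and the strand setting are not given in the sources used here. Because the kit counts 1 tag per transcript end, counts were not divided by gene length. Reads are without stated molecular identifiers, so counts may include PCR copies.

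All files list the same 24413 symbols and no row names no gene (0 rows). Totals ran from 5882912 to 10066661 counts. No 2 libraries of a group agreed within sampling noise: over genes with at least 20 pooled counts, chi-square per degree of freedom was 6.60 to 94.2.

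Genes were filtered with edgeR's filterByExpr (minimum count 10, minimum total 15), leaving 9904, and normalized with TMM factors. Differences were tested with edgeR 4.0.16 (R 4.3.3), using the quasi-likelihood F-test with robust fits, group as the only term, two-sided, and Benjamini-Hochberg adjustment over all genes tested, with a threshold of 0.05. Standard errors are the fitted log2 fold change divided by the square root of F. CPM values use TMM-scaled totals, and log2 CPM a prior count of 2. The biological coefficient of variation was 0.274. The choices of test, lists, naming rule and most alternatives were fixed before the data were examined.

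Of 29 gene lists, 25 had at least 5 tested genes and were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the 25 lists. Named genes are Jagn1 and Cd79a; the 12 largest positive and 12 largest negative log2 fold changes among called genes with an average log2 CPM of at least 2 whose groups do not overlap, leaving out predicted gene models and immunoglobulin segments; and, from each list, up to 4 called members with the smallest p, or 1 or 2 members with the smallest p where none was called. The values of 1 gene that this rule covers are not reported here. Other genes named are said to be chosen after their values were seen. Symbols were matched to GENCODE M21 (GRCm38): 9555 of 9904 tested symbols matched directly and 297 through older symbols.

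The steps were tested on simulated counts for the comparison of knockout and control (9721 genes, real means and library sizes, 200 genes changed). At the threshold 19.4% of genes changed 1.5-fold, 50.7% changed 2-fold and 95.5% changed 4-fold were recovered, and 2 of 112 calls were false. The changed genes were drawn only from those above a minimum mean CPM. Counts were simulated for each gene on its own, without deviations shared across a library. Recovery at low counts and the false calls under such deviations were therefore not tested. Alternatives were DESeq2 1.42.0, limma-voom with sample weights, other scalings, other count filters, fits without robust estimation, a replicate block, a fold threshold of 1.2, and leaving out each library. Alternatives added after seeing the data left out control replicates 1 and 4 together or thinned all libraries to the smallest total. The planned immunoglobulin share, isotype composition and removal of immunoglobulin counts were not analysed here, since no immunoglobulin constant or variable gene is among the symbols used.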

Results

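Gene expression was measured in mouse plasmablasts, the dividing antibody-secreting cells that arise from activated B cells. Splenic B220+ B cells from C57BL/6J mice were cultured for 4 days with 25 µg/ml lipopolysaccharide (LPS), a bacterial cell wall component that drives B cells to divide and to secrete antibody, and CD22-CD138+ cells were then sorted. The question was what the loss of Jagn1, which encodes a membrane protein of the endoplasmic reticulum (ER), changes in the transcripts of these cells. In 4 libraries the mice carried floxed Jagn1 alleles and Mb1-Cre, a recombinase expressed from the B cell gene Cd79a (the Jagn1 knockout). In the 4 control libraries they carried the floxed alleles, and no Cre is listed. The labels state 4 mice per genotype, so the p-values measure the spread between these samples. Libraries were made with a 3′ tag kit, and each file gave raw read counts for 24413 gene symbols. The totals ran from 5882912 to 10066661 counts, with a mean of 7628210 ± 1754573 in the control libraries and 7673508 ± 452912 in the knockout libraries (SD, n = 4 each, exact two-sided permutation p = 1). A count of 0 in a library allowed up to 0.298 to 0.510 CPM, the count scaled to the library's total, at the floor of 3 counts, and intervals and floors cover counting error only.

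The targeted gene was nearly absent from the knockout libraries. Jagn1 lies on chromosome 6 from 113442569 to 113448229 on the plus strand (GRCm38, the mm10 build, GENCODE M21) and has 2 exons. It gave 2, 1, 1 and 1 counts in knockout replicates 1 to 4 and 19, 35, 16 and 99 counts in control replicates 1 to 4. The pooled rate in the knockout was 2.94% of that in the control (exact 95% interval 0.943% to 7.0%, counting error only), and 4.76% (1.5% to 11.6%) without control replicate 4, which gave 99 of the 169 control counts. The log2 fold change was -4.81 ± 0.73 (SE), with an adjusted p of 0.000818 in edgeR's quasi-likelihood test, and -4.16 with limma-voom and sample weights. Every library therefore showed the Jagn1 level that its label gives, although the deleted exons are not given in the sources used here and a 3′ tag reports only the end of a transcript. Cd79a, which encodes the signalling chain of the B cell receptor known as Ig-alpha and is the gene from which Mb1-Cre is expressed, lies on chromosome 7 from 24897381 to 24902197 on the plus strand, with 5 exons. Its level was 304 ± 77.6 CPM in the control and 148 ± 23.5 CPM in the knockout (SD, n = 4 each), a log2 fold change of -1.04 ± 0.19 (edgeR adjusted p = 0.00313), and it was lower in 4 of 4 knockout libraries than in any control library.

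**Figure D1:**
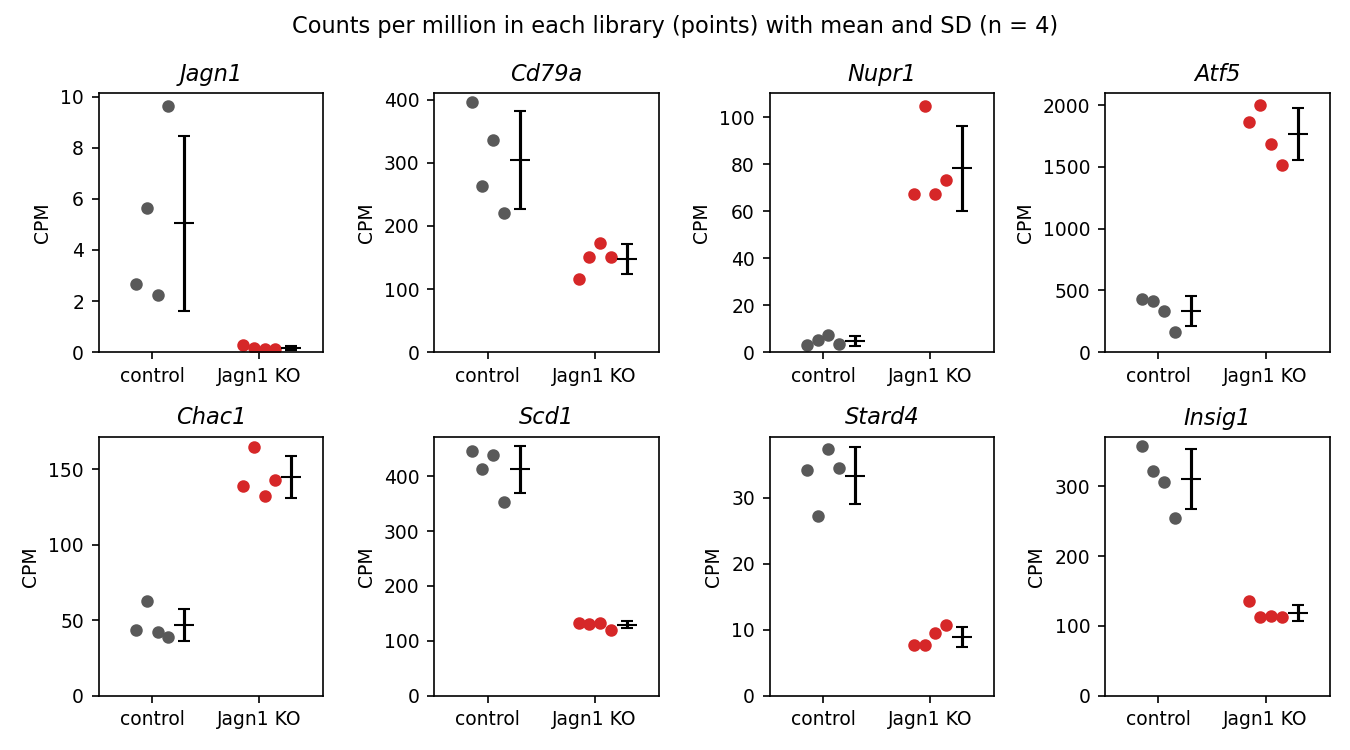
CPM of 8 genes (vertical axes, each starting at 0) in the 4 control libraries (grey points) and the 4 Jagn1 knockout libraries (red points), with the mean and SD of each group as a black bar. For each of the 8 genes the groups do not overlap: Jagn1, Cd79a, Scd1, Stard4 and Insig1 are lower and Nupr1, Atf5 and Chac1 are higher in the knockout.

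Across the transcriptome, loss of Jagn1 went with higher levels of integrated stress response genes and lower levels of SREBP target genes of lipid synthesis. Of 9904 genes tested, 568 differed at an adjusted p under 0.05 (edgeR), 252 higher and 316 lower in the knockout. Of these, 140 were higher and 142 lower by at least 2-fold. All 4 knockout libraries lay above or all lay below all 4 control libraries for 1297 of the 9904 genes tested (13.1%), an arrangement that chance gives to 2.86% of genes. The count depended on single libraries. It was 270 without knockout replicate 2, 344 without knockout replicate 1, 344 without knockout replicate 3, 368 without control replicate 2, 366 without control replicate 3 and 892 without control replicate 4. Control replicates 1 and 4 stood apart from the other libraries, with a root mean square deviation from their group mean of 0.594 and 0.581 on the log2 scale against 0.324 to 0.432 in the other libraries. Leaving both out, an alternative chosen after seeing the data, gave 901 genes.

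**Figure D2:**
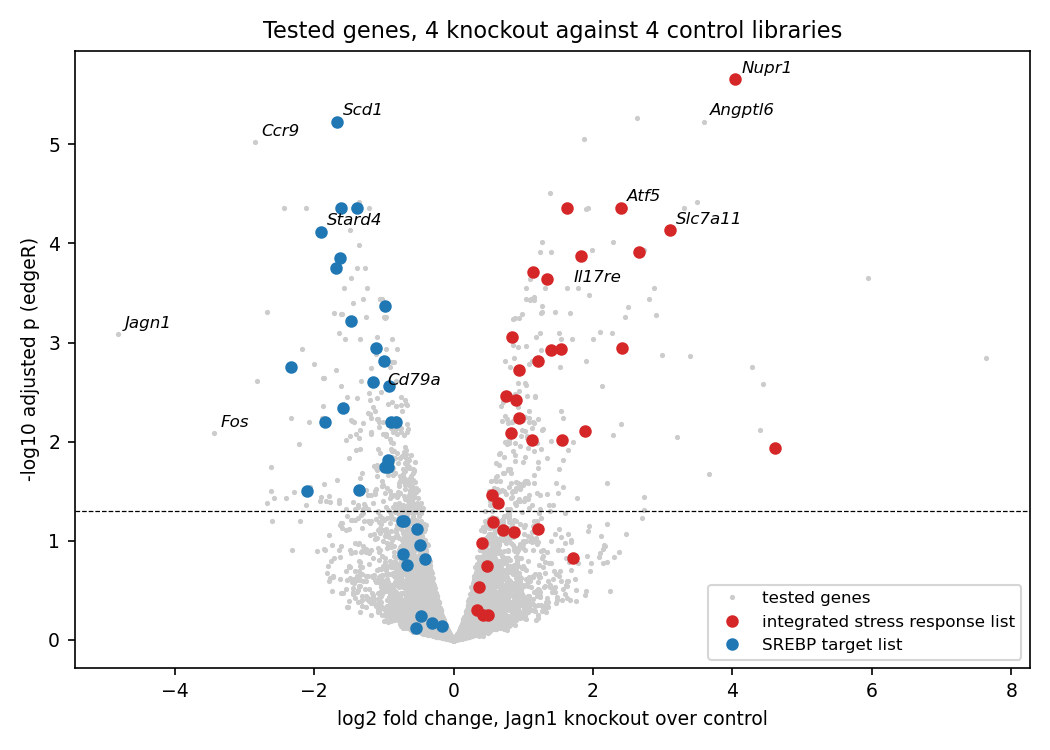
Fitted log2 fold change (horizontal axis, Jagn1 knockout over control) against -log10 of the edgeR adjusted p (vertical axis) for the 9904 tested genes, 4 libraries per group, with the integrated stress response list in red and the SREBP target list in blue; the dashed line marks an adjusted p of 0.05. All 35 tested members of the red list lie to the right of 0 and all 33 of the blue list to the left; the gene farthest to the right, Hspa1a, has 0 counts in the control libraries, so its fitted value is no measured fold.

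The genes with the largest fitted rise, among called genes with an average log2 CPM of at least 2, were Reep6, Irg1, Nupr1, Angptl6, Extl1, Il1rn, Slc7a11, Cela1, Cox6a2, Glrp1, Ccl5 and Aldh1l2. Their log2 fold changes ran from 4.43 for Reep6, which encodes an ER membrane-shaping protein, to 2.74 for Aldh1l2, a mitochondrial folate enzyme. The first 2 rest on control values near the count floor: Reep6 had 0, 7, 3 and 0 counts and Irg1 had 1, 12, 4 and 0 in control replicates 1 to 4. Their log2 fold changes were 5.79 and 5.72 without control replicate 2 and 3.34 and 3.27 without control replicates 1 and 4. Nupr1, a stress-induced nuclear protein, rose from 4.78 ± 1.95 to 78.3 ± 18.0 CPM. Angptl6, a secreted angiopoietin-like protein, rose from 13.7 ± 5.64 to 162 ± 24.5 CPM. Il1rn, the interleukin-1 receptor antagonist, rose from 1.53 ± 0.467 to 15.4 ± 3.31 CPM (all SD, n = 4 each). The genes with the largest fall were Fos, Ccr9, Egfl7, Serpinb1a, Ifi27l2a, Fads2, Egr1, Tnfrsf17, Fam64a, Fgl2, Elovl6 and Hist3h2a, with log2 fold changes from -3.44 to -2.06. Ccr9, the chemokine receptor that directs lymphocytes to the small intestine, fell from 36.5 ± 6.52 to 5.10 ± 1.19 CPM, and Ifi27l2a, an interferon-induced gene, fell from 234 ± 82.7 to 43.2 ± 11 CPM. Fos, an immediate early transcription factor gene, stood at 25.8 CPM in control replicate 1, against 2.37 to 8.22 CPM in the other control libraries and 0.262 to 1.21 CPM in the knockout. Its log2 fold change of -3.44 was -2.40 without control replicate 1, where that of Ccr9 was -2.74, -2.49 without control replicates 1 and 4, and -2.70 with limma-voom. The call of Elovl6 was lost without control replicate 2 or 3 or knockout replicate 2 or 4 (adjusted p up to 0.111), that of Hist3h2a without control replicate 1 or 2 or any 1 knockout replicate (up to 0.116), and that of Tnfrsf17 without knockout replicate 2 (0.0517). Annotated exons of some named genes overlap other genes, so the assignment of their reads is uncertain. On the same strand Hist3h2a shares 708 bases with Trim17, Ccr9 269 with Gm17200, Egfl7 264 with Gm20532 and Sec11a 163 with Nmb, while Egfl7, Gnpnat1, Rpl4, Hspa8 and Xist overlap small RNA genes. On the opposite strand Gnpnat1 shares 3878 bases with Styx, Ccr9 1932 and Aldh1l2 1056 with other genes, and the strand setting of the counting is not given in the sources used here. Smaller opposite-strand overlaps, of at most 580 bases with any 1 gene, were found for Angptl6, Cox6a2, Elovl6, Txndc5, Atf5, Sec63, Man2a1, Slamf7, Plk1, Cdkn1a, Sqstm1, Hspe1, Hspd1 and Ebi3, and Xist shares 1980 bases with Tsix.

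Genes of the integrated stress response, the programme that the transcription factor ATF4 runs after the kinase PERK senses ER stress or the kinase GCN2 senses a shortage of amino acids, rose together. Of 35 tested members, 24 were higher and none was lower (31 higher when adjusted over the list alone), with a median log2 fold change of 1.13. Atf5, a transcription factor gene of this programme, rose from 336 ± 121 to 1766 ± 212 CPM. Chac1, which encodes a glutathione-degrading enzyme, rose from 46.8 ± 10.7 to 145 ± 14.1 CPM, and Slc7a11, the cystine transporter gene, from 3.75 ± 1.91 to 32.4 ± 6.38 CPM (SD, n = 4 each). Camera with a preset inter-gene correlation placed the list above the other genes (adjusted p = 8.33e-49), and the call held with an estimated correlation (adjusted p = 0.00269). Without control replicates 1 and 4 the count of higher members was 28.

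Genes of cholesterol and fatty acid synthesis, which the SREBP transcription factors activate, fell together. Of 33 tested members, 22 were lower and none was higher (29 lower when adjusted over the list alone), with a median log2 fold change of -0.99. Scd1, a fatty acid desaturase gene, fell from 412 ± 42.2 to 129 ± 6.42 CPM. Insig1, which encodes an ER protein that retains the SREBP complex, fell from 311 ± 42.8 to 119 ± 11.7 CPM (SD, n = 4 each). Stard4, a sterol carrier gene, had a log2 fold change of -1.91 ± 0.21. Camera gave an adjusted p of 2.98e-38, which was 0.00269 with an estimated correlation. Without control replicates 1 and 4 the count of lower members was 24.

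These were the only 2 of the 25 lists tested with camera whose calls held with an estimated correlation. With the preset correlation 13 lists passed, 7 upward and 6 downward. Fry, a rotation test of whether the genes of a list move on balance one way, passed 15.

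**Figure D3:**
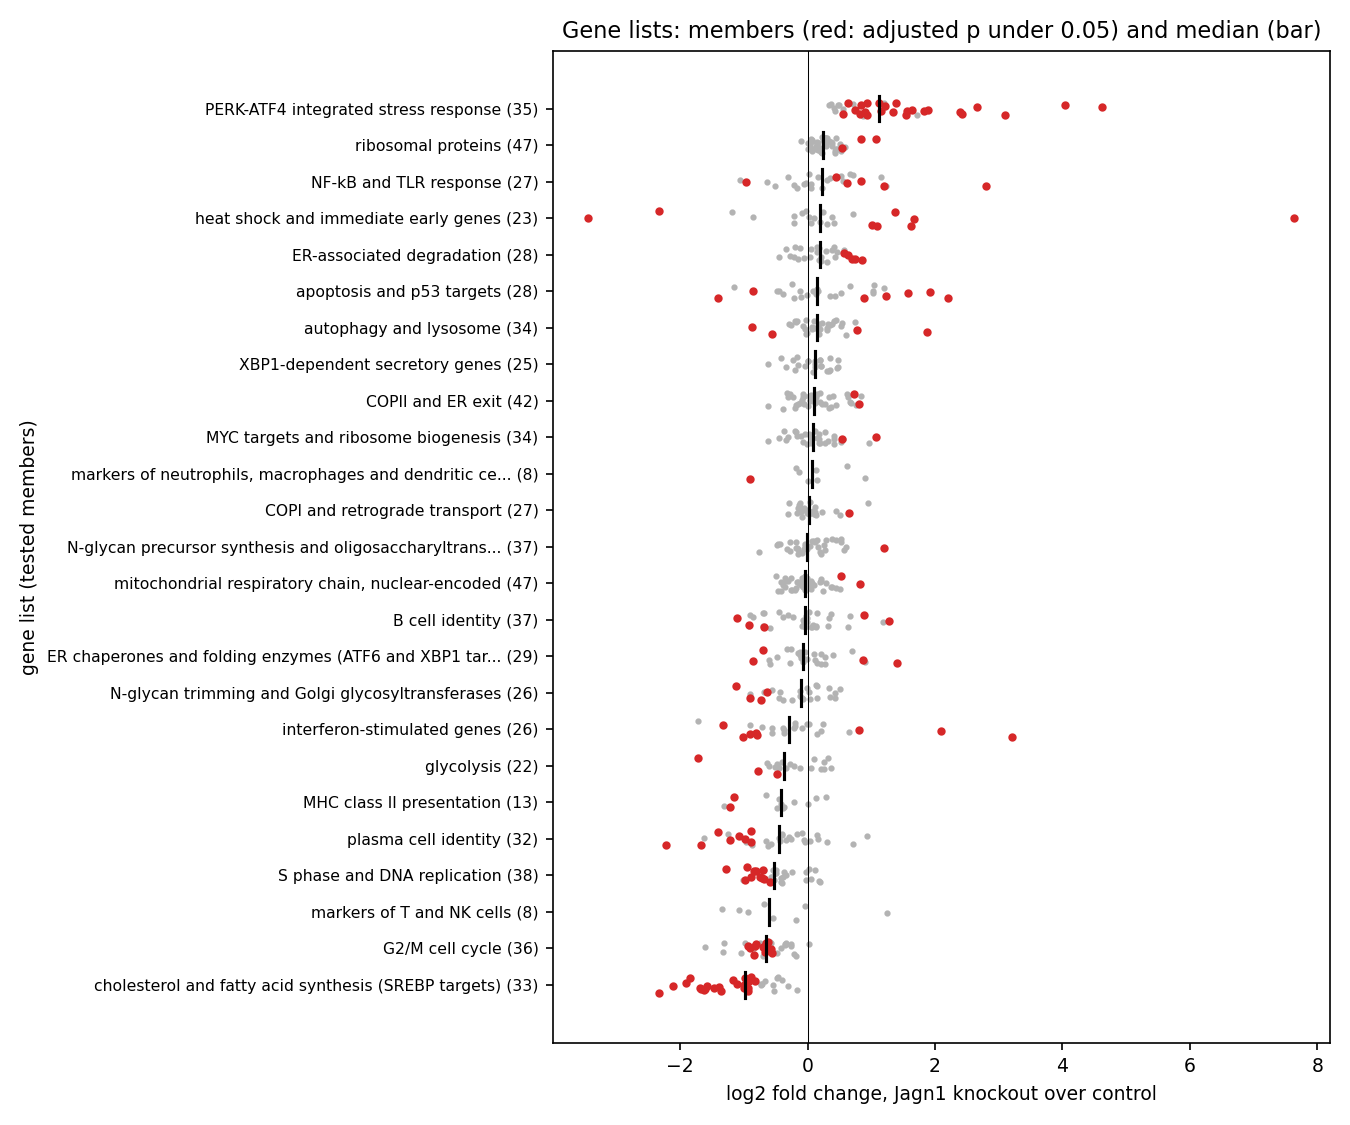
Fitted log2 fold changes (horizontal axis, Jagn1 knockout over control) of the tested members of 25 gene lists (rows, with the number of tested members), 4 libraries per group; red points are members with an edgeR adjusted p under 0.05, grey points the other members and black bars the medians. The integrated stress response list has the highest median (1.13) and the SREBP target list the lowest (-0.99), while ER chaperones centre near 0 (-0.07); the point at the far right is Hspa1a, which has 0 counts in the control libraries.

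Lists of the secretory pathway had small median changes. Calls went in both directions among the ER chaperones and in at most 1 direction within each other list. Among 29 ER chaperones and folding enzymes, 2 were higher and 2 were lower, also when adjusted over the list alone, with a median of -0.07, a mean of 0.03 and a camera adjusted p of 0.727. Ero1l, the ER oxidase gene, rose from 60.7 ± 11.2 to 160 ± 16.6 CPM and Fkbp11 from 88.4 ± 14.3 to 163 ± 20.2 CPM, while Sdf2l1 fell from 180 ± 15.4 to 99.5 ± 10.6 CPM and Txndc5 from 419 ± 86.7 to 259 ± 44.2 CPM (SD, n = 4 each). The call of Txndc5 was lost without control replicate 3 or knockout replicate 1, 2 or 4 (adjusted p up to 0.126). In the ER-associated degradation list 5 of 28 were higher and none was lower, also when adjusted over the list alone, among them Ubxn4, Sel1l and Os9 with log2 fold changes of 0.85, 0.74 and 0.70 (camera adjusted p = 0.00399, and adjusted p = 0.0957 with an estimated correlation). No member of the 25 XBP1-dependent secretory genes passed the edgeR test, also when adjusted over the list alone (camera adjusted p = 0.271, and 0.0453 upward without control replicate 4). At an unadjusted p under 0.05 there were 4, and DESeq2 called 0 and limma-voom 4. Sec11a and Sec63, the members with the smallest p, had log2 fold changes of -0.42 and 0.35. Of 37 genes of N-glycan precursor synthesis 1 was higher, Gnpnat1 (1.2), and of 26 genes of N-glycan trimming and Golgi glycosyltransferases 4 were lower, among them the mannosidase gene Man2a1 (-0.90). Adjusted over the list alone these counts were 1 and 5. Of 42 COPII genes 2 were higher, Ctage5 (0.72) and Tmed3 (0.81), and of 27 COPI genes 1 was higher, Use1 (0.65), or 4 and 1 when adjusted over the list alone. Camera adjusted p was 0.708, 0.174, 0.0618 and 0.428 for these 4 lists, and the first had a median of -0.01 but a mean of 0.05. The trimming list passed downward without control replicate 1 (0.0462). Its called members Mgat1, Mgat4a and Man1a2 lost their calls under 6, 4 and 4 of 18 alternatives. Derl1, of the ER-associated degradation list, lost its call under 6. The COPII list passed upward without control replicate 4 (0.00237), knockout replicate 1 (0.0351) or knockout replicate 2 (0.0398), without control replicates 1 and 4 (0.0304) and with a replicate block (0.0497), and fry passed the COPI list upward (0.0360). Single libraries ended gene calls: that of Gnpnat1 without control replicate 2 or 3 or knockout replicate 1 or 2 (adjusted p up to 0.0858), of Ctage5 without control replicate 3 or knockout replicate 1 or 2 (up to 0.0625), of Tmed3 without control replicate 2 or knockout replicate 2 or 3 (up to 0.101) and of Use1 without control replicate 2 or knockout replicate 2 (up to 0.0755).

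Markers of plasma cells were partly lower. Of 32 tested genes of the plasma cell identity list 8 were lower and none was higher (14 lower and 1 higher when adjusted over the list alone), with a median log2 fold change of -0.44 (camera adjusted p = 1.97e-07, and adjusted p = 0.122 with an estimated correlation). Cd93 fell from 503 ± 11.8 to 218 ± 14.3 CPM, the surface receptor gene Slamf7 from 263 ± 29.9 to 133 ± 13.1 CPM, and Sdc1, which encodes the sorting marker CD138, from 41.2 ± 10.8 to 19.6 ± 2.72 CPM (SD, n = 4 each). Members chosen after their values were seen were the regulators Prdm1, Irf4 and Xbp1, whose log2 fold changes of -0.29 ± 0.15, -0.03 ± 0.20 and -0.39 ± 0.37 did not pass (edgeR adjusted p = 0.327, 0.959 and 0.643). The count of lower members was 3 without knockout replicate 2, 5 without knockout replicate 1, 5 without control replicate 3 and 12 without control replicates 1 and 4. The B cell identity list had 2 higher and 3 lower members of 37, or 3 and 4 when adjusted over the list alone (camera adjusted p = 0.428), among them Irf8 (-0.91) and Cd40 (1.27). Its lower members Cd72 and Cd52 lost their calls under 6 and 3 of 18 alternatives. Of 13 genes of MHC class II presentation 2 were lower, H2-Ob (-1.21) and H2-DMb1 (-1.15), or 7 when adjusted over the list alone, with a camera adjusted p of 0.00169 and an adjusted p of 0.122 with an estimated correlation. The mean of this list in control replicate 2 was 4.83 log2 CPM, against 5.28 to 5.32 in the other control libraries.

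Part of the cell cycle genes were lower. Of 36 G2/M genes 12 fell and none rose, with a median log2 fold change of -0.66, and of 38 S phase genes 11 fell and none rose, with a median of -0.53. Adjusted over the list alone 23 and 15 fell. Plk1, a mitotic kinase gene, fell from 337 ± 65.1 to 176 ± 33.3 CPM, and Mcm3, a gene of the replicative helicase, from 226 ± 13.6 to 141 ± 4.63 CPM (SD, n = 4 each). Camera adjusted p was 1.63e-13 and 1.06e-09, and with an estimated correlation the adjusted p was 0.122 for both. Control replicate 4 had the highest list means, 6.06 and 5.52 log2 CPM, against at most 5.59 and 5.14 in the other control libraries. The G2/M count was 1 without knockout replicate 2, 3 without knockout replicate 3, 5 without control replicate 3 and 14 without control replicates 1 and 4. The S phase count was 4 without knockout replicate 2, 6 without knockout replicate 1, 6 without knockout replicate 3, 7 without control replicate 2 and 11 without control replicates 1 and 4.

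Genes of cell death and the p53 response moved in both directions, with 5 of 28 higher and 2 lower, or 7 and 2 when adjusted over the list alone (camera upward, adjusted p = 0.0242, and adjusted p = 0.122 with an estimated correlation). Cdkn1a, a cell cycle inhibitor gene, rose from 10.8 ± 1.2 to 41.0 ± 5.31 CPM and Bbc3, which encodes the death-promoting protein PUMA, from 161 ± 47.7 to 380 ± 23.2 CPM. Bcl2l11, which encodes the death-promoting protein BIM, fell from 264 ± 29.4 to 99.3 ± 13.9 CPM (SD, n = 4 each). In the autophagy and lysosome list 2 of 34 were higher and 2 lower, or 4 and 2 when adjusted over the list alone. Its lower member Fam134b lost its call under 9 of 18 alternatives. Sqstm1, the autophagy receptor gene, had a log2 fold change of 1.87 ± 0.16 and Npc2, a lysosomal cholesterol carrier gene, -0.88 ± 0.13 (camera upward, adjusted p = 0.0225, adjusted p = 0.151 with an estimated correlation, 0.0591 without control replicate 4 and 0.0878 without control replicates 1 and 4). In the heat shock and immediate early list 6 of 23 were higher and 2 lower, or 6 and 3 when adjusted over the list alone, with a median of 0.20 also when Hspa1a is set at its bound (camera upward, adjusted p = 0.000587, adjusted p = 0.155 with an estimated correlation, and 0.0945 without control replicate 4). The higher members included the chaperone genes Hspa8 (1.38), Hsph1 (1.63), Hsp90aa1 (1.09) and Hspb1 (1.67), and the lower ones were Fos and Egr1. The adjusted p of Egr1 was 0.0813 without a filter on low counts, and it was at 145 CPM in control replicate 1, against 39.3 to 72.0 CPM in the other control libraries.

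The other lists with a camera call lost it with an estimated correlation. Of 27 genes of the NF-kB and TLR response, the pathway that LPS triggers, 5 were higher and 1 was lower (6 and 2 when adjusted over the list alone), with log2 fold changes of 2.81 for the chemokine gene Ccl5 and 0.84 for Ebi3 (adjusted p = 0.0121, and adjusted p = 0.122 with an estimated correlation). Of 47 ribosomal protein genes 3 were higher (6 when adjusted over the list alone), among them Rpl4 (1.07), with 46 of 47 fitted values above 0 (adjusted p = 4.56e-06, and adjusted p = 0.330 with an estimated correlation). Ribosomal protein genes have many processed pseudogene copies, so their counts are uncertain. Of 22 glycolysis genes 3 were lower (4 when adjusted over the list alone), among them Aldoc (-1.71) and Ldha (-0.78), with an adjusted p of 0.0143, an adjusted p of 0.122 with an estimated correlation, and 0.0794 without control replicate 4. Some called members of these lists lost their calls under several of 18 alternatives. These were Pkm (9), Rps6 (5), Cd44 (5), Relb (5) and Rps24 (4). With all 8 libraries and group as the only term, camera at the preset correlation passed none of the remaining lists. The interferon-stimulated list had 3 higher and 5 lower of 26, or 3 and 7 when adjusted over the list alone (adjusted p = 0.0838), with Rsad2 at 2.1 and Ly6e at -0.79. It passed downward without control replicate 2 (0.0439), control replicate 4 (0.0242), knockout replicate 1 (0.0433) or knockout replicate 2 (0.0474). The MYC and ribosome biogenesis list had 2 higher of 34, also when adjusted over the list alone (adjusted p = 0.126, and 0.0271 and 0.0439 upward without control replicates 1 and 2 in turn), the mitochondrial chaperone genes Hspe1 (1.08) and Hspd1 (0.54). The call of Hspd1 was lost with a replicate block and without control replicate 2 or 3 or knockout replicate 1, 2 or 3 (adjusted p up to 0.155). Of 47 nuclear-encoded respiratory chain genes 2 were higher, also when adjusted over the list alone (adjusted p = 0.849), with Uqcrq at 0.82. The call of Atp5g1 in this list was lost under 6 of 18 alternatives.

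Among markers of other cells 1 gene passed the edgeR test. None of 8 tested T and NK cell markers passed it, also when adjusted over the list alone, and their median log2 fold change was -0.61 with 7 of 8 fitted values below 0 (camera adjusted p = 0.271). Of the 8 markers 0 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. Their members with the smallest p, Cd3d and Cd2, stood at 5.63 ± 1.77 and 9.15 ± 1.16 CPM in the control and 2.92 ± 1.33 and 6.30 ± 2.41 CPM in the knockout. Fry passed the list of T and NK cell markers in the downward direction (adjusted p = 0.0234). Of 8 tested myeloid markers 1 was lower, Bst2 (-0.90), which is also on the interferon-stimulated list; the count was also 1 when adjusted over the list alone. Camera gave this list an adjusted p of 0.789 downward, while its median was 0.06 and its mean 0.07. The call of Bst2 was lost without knockout replicate 2 or 3 (adjusted p up to 0.0592). Only 2 erythroid or platelet markers passed the count filter, Itga2b (0.82 ± 0.48) and Tfrc (-0.36 ± 0.25), and only Xist among the sex-linked genes (-0.29 ± 0.13), with edgeR adjusted p of 0.413, 0.506 and 0.240. Xist was the only tested gene of its list, so adjustment over the list alone leaves its unadjusted p, which was under 0.05. DESeq2 and limma-voom called 0 genes of this list. Immunoglobulin constant region and mitochondrially encoded genes were not analysed here.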

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

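In 256 sets of 4 values (named genes, list means and totals in each group), 17 held a library far from the other 3 of its group, 6.64% where chance gives about 5%, so single cases carry little weight. In the knockout, replicate 1 stood above the others for Jagn1 (0.269 CPM, from 2 counts), Insig1 (136 CPM) and Bst2 (25.0 CPM) and below them for Hspb1 (27.5 CPM). Knockout replicate 2 stood above them for Irg1 (20.1 CPM), Nupr1 (105 CPM) and Use1 (390 CPM). Knockout replicate 3 was below for Fos (0.262 CPM), and knockout replicate 4 was below for Sec11a (165 CPM), Mcm7 (64.2 CPM), Ctsd (912 CPM) and Scd1 (119 CPM). Among controls, replicate 3 was above for Ccl5 (3.62 CPM), replicate 4 was above for Aurka (75.7 CPM) and below for Hspd1 (379 CPM), replicate 2 was below for the MHC class II mean (4.83 log2 CPM) and replicate 1 for the apoptosis and p53 mean (4.55 log2 CPM). The reads of Ctsd and Mcm7 are of uncertain assignment, since exons of Ctsd share 808 bases with Gm49369 on the same strand and those of Mcm7 share 84 and 88 with the microRNA genes Mir25 and Mir93 on the same strand and 321 with Ap4m1 on the opposite strand.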

How the results depend on the processing

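Leaving out control replicates 1 and 4 together and thinning to one total were chosen after seeing the data. Of 95 called genes that the naming rule covers, 65 kept direction and call under every alternative that tested them, and none reversed. Of 11 called genes named outside the rule 8 did, and none reversed. These comparisons of single genes leave out the fold threshold of 1.2. Jagn1 and Cd79a kept both under every alternative that tested them, with the same exception. Jagn1 did not pass the strict filter on low counts and was not tested there. The count of 568 genes (252 higher, 316 lower) was 1054 (471, 583) with limma-voom and sample weights, 329 (161, 168) against a fold threshold of 1.2, and 901 (438 higher) without control replicates 1 and 4, where 513 of the 568 stayed called. Leaving out 1 library gave 270 to 892 genes, 137 to 411 higher and 133 to 481 lower; fewer samples enter these fits, and why some raised the count was not tested. DESeq2 called 815, and 567 of the 568 were among them. Thinning gave 561. No scaling moved the median of all genes by over 0.1, and the higher share of calls stayed between 40.6% and 44.4%.

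Leaving out 1 library gave 3 to 11 lower plasma cell identity genes (13 with limma-voom), 1 to 17 lower G2/M genes (19 with limma-voom, 2 against a fold of 1.2) and 4 to 14 lower S phase genes (6 against a fold of 1.2); the cause was not tested. The integrated stress response and SREBP counts moved by less than 1.5 times. An estimated inter-gene correlation left 2 of 13 list calls; the cause was not tested.

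There was no clear sign that the numbers of the libraries pair them. Same-number correlations of deviations from the group mean were -0.003 to 0.066, 0 of 4 pairs exceeded 0.1, and 3 of 8 libraries correlated best with their own number. With 4 pairs this check cannot exclude a pairing. A replicate block gave 509 genes (243 higher, 266 lower). Removing immunoglobulin counts was not run. Depth limits values near the floor of 3 counts, such as the control values of Reep6. At these library sizes, gene spreads and group sizes, 19.4% of simulated genes changed 1.5-fold were recovered. These genes lay above a minimum mean CPM, and depth was not varied in the simulation.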

Other observations

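Gene families taken by symbol were examined after the main results were seen. Their camera p-values are adjusted over these families alone, and some families overlap the lists above, so these values are no separate support. The tests of explanations in this part were also chosen after seeing the data, except those of GC content and the splits of the libraries. Counts of replication-dependent histone genes were low as a family in the knockout. Of 39 tested 12 were lower, none was higher and all 39 fitted values were below 0, with a median log2 fold change of -1.48 (camera adjusted p = 2.37e-19, and adjusted p = 0.0286 with an estimated correlation). Hist1h4d fell from 37.2 ± 14.8 to 9.33 ± 3.66 CPM and Hist1h1e from 128 ± 31.3 to 59.8 ± 23.7 CPM (SD, n = 4 each). The call of Hist1h1e was lost without control replicate 2, without knockout replicate 2 or 3 and without control replicates 1 and 4 together (adjusted p up to 0.113). Most of these transcripts carry no poly(A) tail and the kit primes on poly(A), so the counts of the whole family may not follow its transcript levels. The genes are near-identical copies, so single members are uncertain as well. Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, were higher in 4 of 20 (Eprs, Nars, Sars and Aars; camera adjusted p = 9.82e-06, and adjusted p = 0.0161 with an estimated correlation), and 7 of the 20 are on the integrated stress response list. The call of Aars was lost under 11 of 18 alternatives, namely library totals alone, no filter on low counts, a replicate block, leaving out control replicates 1 and 4 together, and leaving out any 1 library except control replicate 1 (adjusted p up to 0.141). None of 17 mitochondrial synthetases passed in edgeR, DESeq2 or limma-voom, and 0 had an unadjusted p under 0.05, with a median of -0.19 (camera adjusted p = 0.391); the difference between the families was not tested.

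Amino acid transporters had 6 higher and 1 lower of 23, with a median log2 fold change of 0.18 and 14 fitted values above 0. Camera adjusted p was 1.32e-05, and 0.0277 with an estimated correlation. Of the 23, 4 are on the integrated stress response list, and all 4 are among the 6 higher. Slc3a2 rose from 193 ± 64.8 to 681 ± 59.2 CPM and Slc7a3 from 59.3 ± 23.5 to 227 ± 11.1 CPM. Hsp and Dnaj chaperones had 10 higher and none lower of 54 (adjusted p = 8.65e-09, and adjusted p = 0.0143 with an estimated correlation). Hspa1a had 0 counts in the control and 97 in the knockout, at least 32.1-fold higher against a floor of 3 counts over the group, and its near-identical copy Hspa1b had 0 and 33. Proteasome subunits (1 of 38 higher, adjusted p = 0.391), integrins (0 of 13 with edgeR and DESeq2, 1 with limma-voom, 3 at an unadjusted p under 0.05) and chemokine receptors (0 higher, 2 of 8 lower, Ccr9 and Ccr10) passed no family test. The call of Ccr10 was lost without control replicate 3 or knockout replicate 1, 2 or 4 (adjusted p up to 0.122).

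Of 35 splits of the 8 libraries into 4 and 4, only the real one called genes. It gave 568, and the highest of the others gave 0. A share of 1 of 35 is the smallest that this test can reach, so chance is made unlikely but not excluded. Every other split mixes knockout and control libraries within a group, which widens the spread there, so the contrast with 0 overstates the evidence. For the 13 lists with the preset correlation the real split was also the only 1 of 35 with a result as large. Another split reached 11. It held control replicates 1 to 3 with knockout replicate 4 and so kept part of the real difference. Splits with 2 libraries of each genotype in both groups gave 0 to 10 lists. The preset test can therefore pass many lists where the genotypes are evenly mixed. With an estimated correlation the real split gave 2 lists (1 of 35) and the highest of the others 0.

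The first pattern weighed is the rise of integrated stress response genes with the fall of SREBP targets. Removing a trend on the GC content of each gene's longest annotated transcript kept 91.9% of the first median and 99.6% of the second. This argues against such a trend as the whole cause. The kit reads only the 3′ end, whose GC content was not examined, so a bias from it stays open. Leaving out control replicates 1 and 4 kept the calls of 23 of 24 and 21 of 22 members (95.5% for the second list). That argues against these libraries as the whole cause. Stress from handling before lysis stays open: immediate early genes had a median log2 fold change of -0.0314 (7 of 15 above 0), but 6 of 8 heat shock genes were higher. The mean log2 CPM of the 15 immediate early genes, compared between the groups, gave an exact two-sided permutation p of 0.0857. Mb1-Cre goes with the knockout in all 8 libraries, so its own effect was not tested. A response to the loss of Jagn1 may account for the pattern, as a hypothesis.

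The second pattern is Il17re, an interleukin receptor gene on chromosome 6 from 113458484 to 113470758, which starts 10254 bases downstream of Jagn1 on the same strand. Il17re rose from 29.4 ± 6.35 to 91.1 ± 23.5 CPM (SD, n = 4 each), a log2 fold change of 1.63 ± 0.21 (edgeR adjusted p = 0.00028). The 19 other tested genes within 500 kb had a median of 0.041 and an SD of 0.592, with 10 of 19 above 0, which argues against a like rise of the whole region, and 0 genes share an annotated exon with it; Ogg1 (1.29), Il17rc (1.08), the next gene downstream, and Tada3 (0.87) were at 1 to 6 CPM and did not pass (edgeR adjusted p = 0.144, 0.418 and 0.448), so a rise of single neighbours stays open. Transcripts that run from the deleted Jagn1 allele into Il17re may add to its counts; its gain of 61.7 CPM was 12.7 times the loss of 4.88 CPM at Jagn1, which gene counts cannot decide without reads across the junction. Regulation of Il17re in response to the loss of Jagn1 stays open as well.

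The third pattern is the lower Cd79a. Its log2 fold change of -1.04 has a 95% interval of -1.44 to -0.65, which holds the value of -1 that the loss of 1 allele of 2 to the Cre insertion would give, so that is a candidate explanation. A like fall of B cell identity genes is argued against, because the 37 tested genes of that list, which does not hold Cd79a, had a median of -0.037 with an SD of 0.577, and 1 of them had a fitted value as low as that of Cd79a. The MHC class II and plasma cell identity lists had medians of -0.42 and -0.44. A smaller fall of other genes of these cells therefore stays open as a part of the cause. Sequence of another strain around the insertion cannot be told apart: 5 of 90 genes within 5 Mb were called (5.56%, exact 95% interval 1.83% to 12.5%) against 5.72% elsewhere (Fisher's exact two-sided p = 1), and 90 genes are too few to exclude a small excess.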
